A study of Mus musculus with 6 samples.

How the data were processed

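Bulk RNA sequencing measured gene expression in cortex of C57BL/6 mice after middle cerebral artery occlusion (MCAO), a surgical model of ischaemic stroke. Per the labels, 3 samples came from animals given green fluorescent protein (GFP), the control, and 3 from animals given NeuroD1, a proneural transcription factor. Total RNA was extracted with a column kit and libraries were made with standard Illumina protocols, per the labels' protocols. The time after stroke, the vector and the sex of the animals are not given in the sources used here. The labels number the samples but do not say that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

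The deposited values are raw read counts per gene symbol, made with featureCounts on an mm10 gene file, per the file headers. HISAT2 2.0.1, DESeq2 1.16.1 and build GRCm38 are named in the submitters' processing notes without their roles. The strand setting, the annotation release and any read filter are not given in the sources used here. Without a stated strand setting, reads of a gene and an overlapping antisense gene cannot be told apart. Genes with near-identical copies, such as Ly6c1 and Ly6c2 or members of the H2 and histone families, are uncertain because the treatment of reads that map to several places is not given either. The table holds 24421 gene symbols, of which 4989 had 0 counts in all 6 libraries. Every column was matched to its sample by the sample description in the labels, and no column was left unused.

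Total counts were 9698795, 7753101 and 8503169 in the GFP libraries (replicates 1, 2 and 3) and 13440244, 11239522 and 10843273 in the NeuroD1 libraries. A single count therefore corresponds to between 0.0744 and 0.129 CPM (counts scaled to a common library size) before TMM scaling, and every NeuroD1 library was deeper than every GFP library. Within each group, pairs of libraries had a chi-square per gene of 35.4 to 133, against about 1 from sampling noise alone, so no pair was treated as a duplicate.

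The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, treatment as the only term and no replicate block. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 14852 genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group.

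Before the data were examined, 33 gene lists were fixed for cell types, processes, neighbouring brain regions and RNA quality, and 31 had at least 3 tested members. The list of red blood cell transcripts could not be tested, because the haemoglobin genes were listed at 0 in all libraries and no member had enough counts. The list of mitochondrial transcripts has no rows in the table used here, nor do Scn2a, Trac and Trbc2. Lists were tested with camera of limma 3.58.1, two-sided, with its preset inter-gene correlation of 0.01 and adjustment over the 31 lists, and beside it with an estimated correlation and with fry. Members of a list were also counted as past the threshold when their edgeR p-values were adjusted over the list alone. The mean of each list per library, relative to the GFP mean of each gene, was compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

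The rule for named genes, also fixed before, took Neurod1, then the 10 highest and 10 lowest genes past the threshold, then the 3 members of each list with the smallest p. No gene was eligible for the second part. Genes named outside this rule are said to have been chosen after their values were seen. The 5 lists described first were also picked from the 31 after their values were seen.

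The alternatives planned before were DESeq2 1.42.0 (Wald test), limma-voom, size factors or upper quartile scaling, no filter or a stricter filter, a replicate block, other thresholds, and leaving out each library in turn. Alternatives added after the data were seen were offsets for transcript length and GC content, a fit without the 45S ribosomal RNA precursor Rn45s, a robust prior variance, DESeq2 under the left-out libraries, block and offsets, DESeq2 with its filtering tuned to 0.1, list enrichment among DESeq2 calls, and 8 further gene lists, adjusted as a family of 8. The offsets were natural splines with 4 degrees of freedom of each library on log2 transcript length and GC, from GENCODE M21 on GRCm38, where 14769 of the tested genes (99.4%) had a length.

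The tests were tested on simulated data with the real means, library sizes and dispersions of the 14852 genes, with 200 genes changed in each of 5 simulations of NeuroD1 against GFP. The changed genes were drawn from those with a mean above 5 CPM, so recovery below that level was not measured. The edgeR test recovered 10.2% of the 2-fold and 88.4% of the 4-fold changes, with 5.8 false calls on average. DESeq2 recovered 36.8% and 95.6%, with 40 false calls on average. With 200 genes changed per simulation, this is a larger share of its calls than the adjusted threshold allows. Counts of DESeq2 calls in the real libraries may include more false calls than their threshold states. That share depends on how many genes change, so the simulation does not give it for the real libraries. Camera called a list of changed genes in 5 of 5 simulations and a list of unchanged genes in 0 of 5. The simulated genes varied independently of each other, so this says nothing of lists whose members vary together. Recovery in the real libraries may differ for the same reason.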

Results

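Bulk RNA sequencing covered 6 cortex samples of mice after MCAO, 3 given GFP and 3 given NeuroD1. The GFP libraries held 7753101 to 9698795 counts and the NeuroD1 libraries 10843273 to 13440244. The comparison asks how NeuroD1, a transcription factor that directs cells towards a neuronal fate, alters gene expression in the stroke-injured cortex and its blood vessels.

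Neurod1 averaged 33.8 ± 17.4 CPM in the NeuroD1 libraries and 5.26 ± 1.31 CPM in the GFP libraries (SD, n = 3 each), a 6.39-fold difference. Endothelial and blood-brain barrier genes were lower with NeuroD1, and 11 of 22 passed the threshold when adjusted over the list alone, among them the angiopoietin receptor Tek, 2.75-fold lower. Markers of infiltrating myeloid cells (9 of 12 members), fibroblast and scar matrix genes (10 of 15) and cell cycle genes (13 of 15) were higher by the same criterion. Neuronal, synaptic and interneuron lists were not called in either direction with all libraries. Without NeuroD1 replicate 2 the pan-neuronal and synapse lists were called higher by camera at its preset correlation, and 0 lists with an estimated one. Over all 14852 genes, 0 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, so these differences rest on the smaller families of tests. The lists counted here were picked after their values were seen, which adjustment within a list does not cover. With an estimated inter-gene correlation camera called 0 of 31 lists. That correlation was 0.927 for cell cycle, 0.584 for scar matrix, 0.575 for endothelial and 0.502 for myeloid genes. The members counted here are therefore not separate observations. At its preset correlation, 7 of 10 splits of the libraries, the real one included, called at least as many lists as the real split. At an unadjusted edgeR p under 0.05 there were 3564 genes, while limma-voom called 0 after adjustment and DESeq2 1374. In simulated data with 200 changed genes DESeq2 made more false calls than its threshold allows. That share depends on how many genes change, so it is not known for the 1374. Leaving out 1 library took the endothelial count to 0 (GFP replicate 2, NeuroD1 replicate 1 or NeuroD1 replicate 2), the scar count to 0 (GFP replicate 1 or 2), the cell cycle count to 0 (GFP replicate 1) and the myeloid count to 5 (GFP replicate 3 or NeuroD1 replicate 1).

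**Figure D1:**
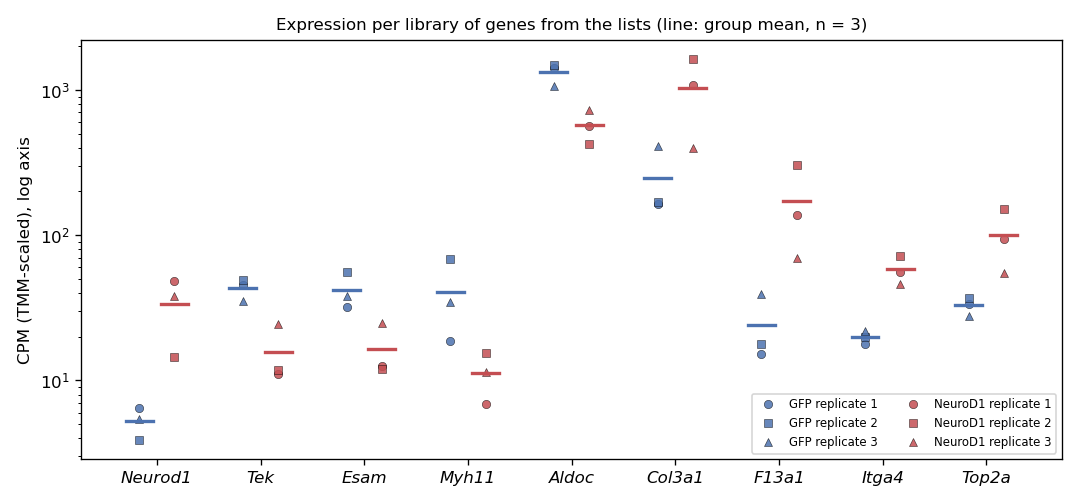
TMM-scaled CPM on a log axis for 9 genes from the lists, with a point for each of the 6 libraries (circle, square and triangle for replicates 1, 2 and 3) and a line at each group mean. Tek, Esam, Myh11 and Aldoc lie lower in every NeuroD1 library than in any GFP library, Neurod1, F13a1, Itga4 and Top2a lie higher, and Col3a1 overlaps between the groups.

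The smallest edgeR adjusted p was 0.136, shared by 497 genes. At an unadjusted p under 0.05 there were 3564 genes, 1851 higher and 1713 lower with NeuroD1, or 24.0% of those tested against 5% by chance. In 4391 genes (29.6%, against 10% by chance) the groups did not overlap. Among the alternative tests, limma-voom called 0 genes, with a smallest adjusted p of 0.149, and DESeq2 called 1374, of which 774 were higher and 600 lower. Of the DESeq2 calls that edgeR tested, 1356 of 1357 had an unadjusted edgeR p under 0.05. Both tests used the same counts and the unadjusted threshold is looser, so this overlap is not independent support. In the simulated data, with 200 changed genes, DESeq2 made 40 false calls on average, more than its threshold allows. The share of false calls depends on how many genes change, so the simulation does not give it for the 1374 calls. It stays unknown for them, and for the DESeq2 counts and enrichment of lists that rest on them. The smallest chi-square per gene of any pair of libraries was across the groups, between GFP replicate 1 and NeuroD1 replicate 3 (30.4, against 35.4 to 133 within groups). Without NeuroD1 replicate 2, edgeR called 1 gene, Neurod1. The DESeq2 count was 162 without GFP replicate 2, 224 without GFP replicate 3 and 256 without NeuroD1 replicate 1, and was 2380 without NeuroD1 replicate 3.

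Neurod1 (chromosome 2, 79452521 to 79456751, minus strand, protein coding, GRCm38) had 64, 29 and 50 counts in GFP replicates 1, 2 and 3 and 644, 151 and 428 in the NeuroD1 replicates, so it was higher in 3 of 3 NeuroD1 libraries. Its log2 fold change was 2.68 (SE 0.45), with an edgeR adjusted p of 0.136 over all genes and 0.0053 over its list alone. The adjusted p was 1.08e-05 with DESeq2 and 0.0421 by edgeR without NeuroD1 replicate 2, the library with the fewest Neurod1 counts of its group. Counts are per gene, so reads from a delivered copy and from the mouse gene were not separated. The gene lies within the annotated span of Cerkl on the same strand, which held 0.787 ± 0.551 CPM with GFP and 1.03 ± 0.303 CPM with NeuroD1 (SD, n = 3).

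Of the 31 lists tested with camera at its preset correlation, 12 passed the threshold, 7 higher and 5 lower with NeuroD1. With an estimated correlation 0 passed (smallest adjusted p = 0.684), as with any 1 library left out (smallest 0.631, without GFP replicate 3) or with the length and GC offsets (smallest 0.55), and with fry's directional test 0 passed (smallest adjusted p = 0.326). Fry's mixed test, which asks for change in either direction, passed 2 lists, the proneural and the neurotrophic (adjusted p = 0.0406 each). The proneural list holds Neurod1, the delivered gene, and was not tested without it. The list means of the groups did not overlap in 9 lists, against 3.1 expected by chance, and each of these had an exact permutation p of 0.1 (0.344 after adjustment), the smallest 3 against 3 can give. Among all tested genes the groups did not overlap in 29.6%, a similar share, so this count does not set the lists apart from other genes. Among DESeq2 calls, a test chosen after the data were seen, 5 lists were enriched by Fisher's exact test over genes, which are not independent replicates. These were endothelial genes among the lower calls (11 of 22, adjusted p = 7.78e-09) and, among the higher, scar matrix (8 of 15, 3.04e-06), myeloid (8 of the 13 DESeq2 tested, 8.89e-07), cell cycle (10 of 15, 7.78e-09) and disease-associated microglia genes (6 of 18, 0.00226). Other divisions of the same 6 libraries into 3 and 3 gave between 4 and 20 called lists at the preset correlation, so such a call alone does not tie a list to the treatment.

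**Figure D2:**
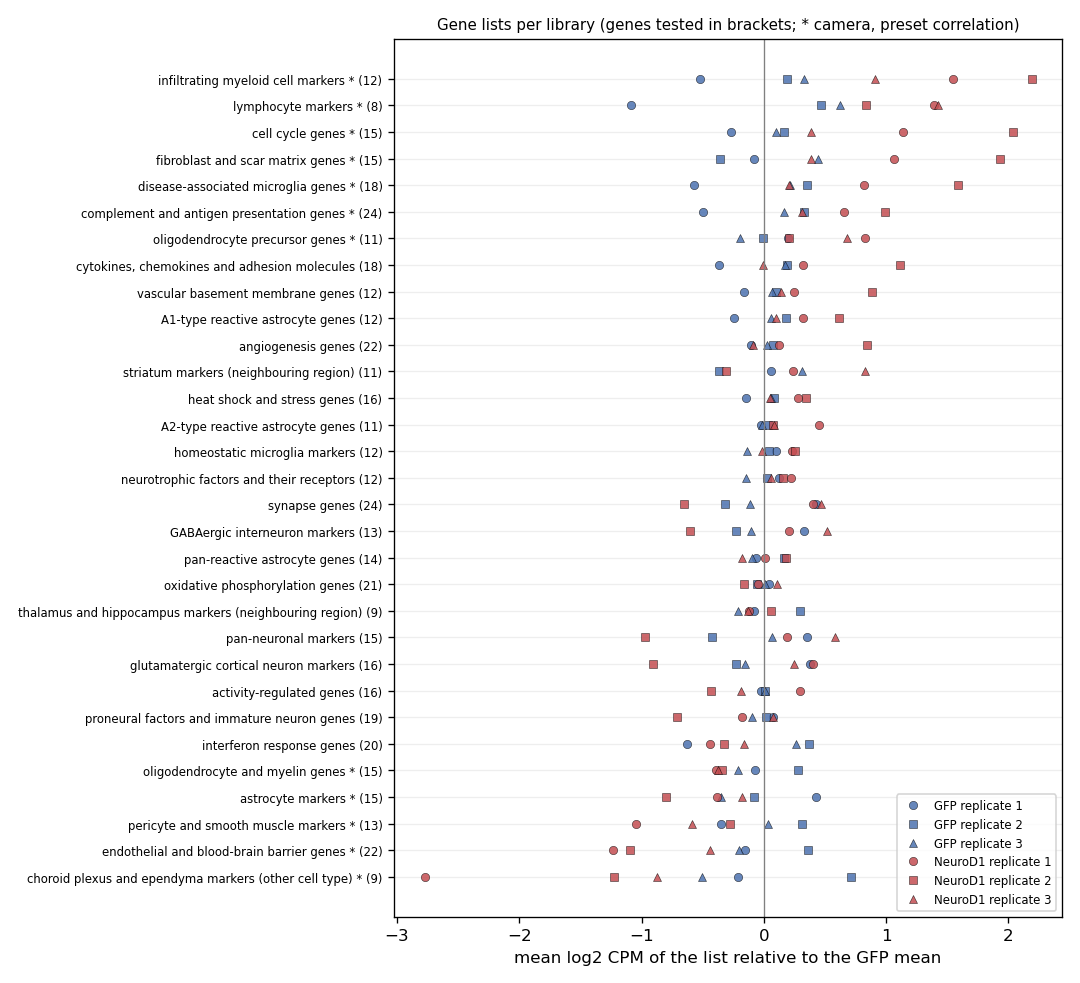
Mean log2 CPM of each of the 31 tested lists in each library, relative to the GFP mean, with the number of genes in brackets and an asterisk for lists called by camera with the preset correlation. Endothelial and choroid plexus lists lie lower in all NeuroD1 libraries than in any GFP library and myeloid and cell cycle lists higher, while NeuroD1 replicate 2 has the lowest pan-neuronal mean (-0.97) and the highest myeloid mean (2.19).

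Endothelial and pericyte markers were mostly lower with NeuroD1, while basement membrane and angiogenesis genes moved both ways. The endothelial and blood-brain barrier list had a median log2 fold change of -0.86 (camera adjusted p = 1.56e-08; adjusted p = 0.684 with an estimated correlation), and 21 of its 22 members had lower fitted levels. Past the threshold over the list alone were 11 members, against 0 over all genes and 11 with DESeq2. Tek (chromosome 4, 94739289 to 94874976) averaged 15.8 ± 7.50 CPM against 43.4 ± 7.35 with GFP. Esam and Pecam1, both adhesion molecules of endothelial junctions, were 2.54-fold and 2.07-fold lower (log2 fold changes -1.34, SE 0.35, and -1.05, SE 0.30). Tek, Esam and Pecam1 each had an adjusted p of 0.0252 over the list alone and were lower in 3 of 3 NeuroD1 libraries than in any GFP library. The count over the list alone was 0 without GFP replicate 2, without NeuroD1 replicate 1 or without NeuroD1 replicate 2, while the list median lay between -1.09 and -0.69 whichever library was left out.

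In the pericyte and smooth muscle list 8 of 13 members were lower and 1 higher over the list alone (0 over all genes, and 3 lower and 1 higher with DESeq2), with a median of -0.66 (camera adjusted p = 0.00291; adjusted p = 0.684 with an estimated correlation). The pericyte gene Higd1b was 4.23-fold lower (log2 fold change -2.08, SE 0.52) and Myh11, smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372), was 3.62-fold lower (-1.86, SE 0.49). Anpep, an aminopeptidase that macrophages also express, went the other way and was 3.64-fold higher (1.87, SE 0.51). All 3 had an adjusted p of 0.0222 over the list alone. Myh11 was 2.37-fold lower without GFP replicate 2 and Anpep 2.02-fold higher without NeuroD1 replicate 2. The count of lower members was 0 without GFP replicate 2, GFP replicate 3 or NeuroD1 replicate 1, and 3 with offsets for transcript length and GC.

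Vascular basement membrane genes moved both ways, with 6 of 12 higher and 2 lower over the list alone, and the list was not called (median 0.72, camera adjusted p = 0.054; 0.847 with an estimated correlation). Lamb1 and Nid1, structural proteins of basement membranes, were 2.37-fold and 3.16-fold higher, and Lama5, a laminin chain of mature vessels, was 2.33-fold lower (adjusted p = 0.0149 over the list alone for each). Nid1 was 2.09-fold higher without NeuroD1 replicate 2. This list passed without any 1 of GFP replicates 2 and 3 and NeuroD1 replicates 1 and 3, with its smallest camera adjusted p of 0.00962 without NeuroD1 replicate 1 (adjusted p = 0.73 with an estimated correlation). With all libraries it also passed with upper quartile scaling, with no filter or without Rn45s (adjusted p from 0.646 with an estimated correlation). It did not pass without GFP replicate 1 (adjusted p = 0.346) or NeuroD1 replicate 2 (median 0.43, adjusted p = 0.222). Its counts of higher and lower members over the list alone were 0 and 0 without GFP replicate 2, 2 and 1 without GFP replicate 3, 3 and 2 without GFP replicate 1, 3 and 1 without NeuroD1 replicate 2, 6 and 1 without NeuroD1 replicate 1, and 2 and 1 with the length and GC offsets. Among angiogenesis genes 3 of 22 were higher and 2 lower over the list alone, and the list was not called (median 0.38, camera adjusted p = 0.488). These counts were 1 and 1 without GFP replicate 2, 1 and 0 without GFP replicate 3 or NeuroD1 replicate 1, and 10 and 2 without NeuroD1 replicate 3. The matrix protein gene Thbs1, an inhibitor of angiogenesis, was 11.6-fold higher (190.7 ± 170.5 against 16.4 ± 2.23 CPM, SD, n = 3; adjusted p = 0.0072 over the list alone). It was 5.68-fold higher without NeuroD1 replicate 2. Vegfa, the main endothelial growth factor, was lower (28.4 ± 3.57 against 56.8 ± 6.53 CPM; adjusted p = 0.0085), and Hif1a, the oxygen-sensing transcription factor, was 2.82-fold higher (adjusted p = 0.0261).

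**Figure D3:**
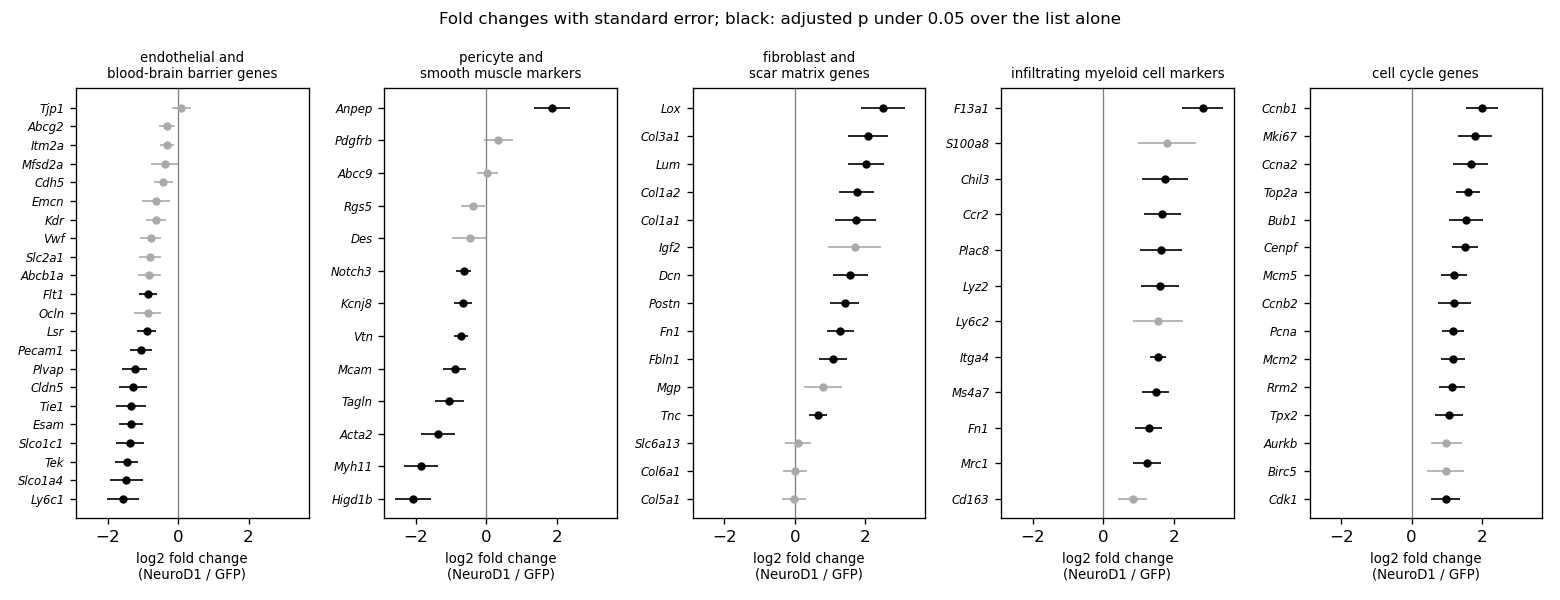
Log2 fold change (NeuroD1 against GFP) with its standard error for every tested member of 5 lists, in black where the adjusted p over the list alone is under 0.05. Black members lie below 0 in the endothelial panel (11 of 22) and above 0 in the scar matrix (10 of 15), myeloid (9 of 12) and cell cycle (13 of 15) panels, and the pericyte panel has 8 below and Anpep above.

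Fibroblast and scar matrix genes had a median log2 fold change of 1.42 (camera adjusted p = 1.48e-05; adjusted p = 0.684 with an estimated correlation), with 10 of 15 members higher over the list alone, 0 over all genes and 8 with DESeq2. The collagen-binding proteoglycan gene Lum was 4.05-fold higher, the collagen cross-linking enzyme gene Lox 5.65-fold higher and the fibrillar collagen gene Col3a1 (chromosome 1, 45311538 to 45349706) 4.18-fold higher, at 1037 ± 619.5 against 247.9 ± 139.1 CPM (SD, n = 3; adjusted p = 0.0229 over the list alone for each). Lox was 2.92-fold higher without NeuroD1 replicate 2. The collagen gene Col5a1, chosen after its values were seen, had a log2 fold change of -0.023 (SE 0.35). The count was 0 without GFP replicate 1 or GFP replicate 2 and 6 without NeuroD1 replicate 2, where the median was 0.87.

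Markers of infiltrating myeloid cells had a median of 1.59 (camera adjusted p = 2.14e-08; adjusted p = 0.684 with an estimated correlation), and 9 of 12 members were higher over the list alone, 0 over all genes and 7 with DESeq2. The integrin gene Itga4, which leukocytes use to enter tissue (chromosome 2, 79255426 to 79333123), was 2.94-fold higher, a log2 fold change of 1.56 (SE 0.23; adjusted p = 0.0012 over the list alone). F13a1, a clotting factor subunit made by macrophages, was 7.07-fold higher (adjusted p = 0.0066; 4.34-fold without NeuroD1 replicate 2) and the macrophage gene Ms4a7 2.80-fold higher (adjusted p = 0.0152). Fn1 counts in both this list and the scar matrix list. Bulk counts of these genes do not tell infiltrating cells from macrophages resident in the sampled tissue. Between 5 and 12 members passed when a library was left out, with 5 without GFP replicate 3 or NeuroD1 replicate 1 and 6 without NeuroD1 replicate 2.

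Cell cycle genes had a median of 1.21 (camera adjusted p = 2.14e-08; adjusted p = 0.684 with an estimated correlation), with 13 of 15 members higher over the list alone, 0 over all genes and 10 with DESeq2. The DNA topoisomerase gene Top2a (chromosome 11, 98992943 to 99024189) was 3.04-fold higher (99.9 ± 48.2 against 32.9 ± 4.60 CPM), the cyclin gene Ccnb1 3.97-fold and the kinetochore gene Cenpf 2.86-fold (adjusted p = 0.0141 over the list alone for each, higher in 3 of 3 NeuroD1 libraries). No member passed without GFP replicate 1, 8 passed without GFP replicate 3 and 7 without NeuroD1 replicate 2, where the median was 0.76.

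Further immune lists were also called by camera at the preset correlation. Disease-associated microglia genes had a median of 0.73 (adjusted p = 0.000653), complement and antigen presentation genes 0.48 (adjusted p = 0.000232) and lymphocyte markers 1.36 (adjusted p = 0.00255), against adjusted p = 0.819, 0.819 and 0.684 with an estimated correlation. In these lists 0 of 18, 0 of 24 and 0 of 8 members passed over the list alone, and 6, 5 and 2 with DESeq2, all higher. Without NeuroD1 replicate 3, 6 microglia and 7 complement members were higher over the list alone, and the complement count was 3 without GFP replicate 1 and 1 without NeuroD1 replicate 2. With no filter 5 microglia and 7 complement members were higher, and with the length and GC offsets 2 microglia, 6 complement and 2 lymphocyte members. The microglia list was also enriched among the higher DESeq2 calls (6 of 18 members against 0.912 expected, Fisher's exact test, adjusted p = 0.00226). The members with the smallest p were Gpnmb (5.61-fold, and 3.06-fold without NeuroD1 replicate 2, a lysosomal glycoprotein gene), C3 (1.84-fold, the central complement component) and Cd8b1 (3.87-fold, a T cell co-receptor), with adjusted p = 0.0623, 0.0562 and 0.0524 over the list alone. The microglia call was lost without GFP replicate 1 (adjusted p = 0.0603), and its median was 0.38 without NeuroD1 replicate 2. The lymphocyte call was lost without GFP replicate 1 (median 0.69, adjusted p = 0.229) or NeuroD1 replicate 3 (adjusted p = 0.0725), and the complement median was 0.31 without GFP replicate 1 and 0.30 without NeuroD1 replicate 2. Homeostatic microglia markers, cytokines and chemokines, and interferon response genes were not called (medians 0.21, 0.52 and -0.42; adjusted p = 0.428, 0.119 and 0.0893), and 0 of their 12, 18 and 20 members passed over the list alone. Without GFP replicate 1 the interferon list was called, with a median of -0.64 (adjusted p = 0.00016), and 10 members were lower and 1 higher over the list alone, against an adjusted p of 0.977 with an estimated correlation. Its median was -0.25 without GFP replicate 3. The cytokine list was called without any 1 of GFP replicates 2 and 3 and NeuroD1 replicates 1 and 3 (adjusted p from 0.0188), against adjusted p from 0.678 with an estimated correlation. Without NeuroD1 replicate 3, 2 of its members were higher over the list alone. With the length and GC offsets it was also called (adjusted p = 0.0381; 0.709 with an estimated correlation). The cytokine median was 0.19 (adjusted p = 0.767) without NeuroD1 replicate 2 and 0.34 (0.521) without GFP replicate 1, and the homeostatic median 0.12 without NeuroD1 replicate 2 and 0.36 without NeuroD1 replicate 3.

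Glial lists were called in different directions. Astrocyte markers had a median of -0.43 (camera adjusted p = 0.00324; adjusted p = 0.819 with an estimated correlation), and 3 of 15 members were lower over the list alone, namely the calcium-binding protein gene S100b (2.14-fold), the glycolytic enzyme gene Aldoc (2.32-fold) and Ndrg2 (2.17-fold), with adjusted p = 0.0227, 0.029 and 0.0472. Without GFP replicate 1 the astrocyte call was lost (median -0.22, adjusted p = 0.346), and without NeuroD1 replicate 2 the median was -0.27. The count over the list alone was 1 without GFP replicate 1 and 0 without GFP replicate 2 or NeuroD1 replicate 1. Oligodendrocyte and myelin genes had a median of -0.34 (adjusted p = 0.0228; 0.819 with an estimated correlation), and 1 of 15 members, Opalin, a myelin membrane gene, was lower over the list alone (1.92-fold, adjusted p = 0.0444). In this list 0 members passed whichever of the 6 libraries was left out. That call was lost without GFP replicate 1, GFP replicate 2 or NeuroD1 replicate 3 (adjusted p = 0.0543, 0.0912 and 0.111). Oligodendrocyte precursor genes had a median of 0.71 (adjusted p = 0.0316; 0.684 with an estimated correlation), and 2 of 11 were higher over the list alone, the proteoglycan gene Vcan (1.85-fold) and the growth factor receptor gene Pdgfra (2.23-fold), which fibroblasts also express. It was lost without GFP replicate 1 (adjusted p = 0.0539) or NeuroD1 replicate 3 (adjusted p = 0.112). Its count over the list alone was 0 without GFP replicate 2, GFP replicate 3 or NeuroD1 replicate 1 and with the length and GC offsets, 4 without GFP replicate 1 and 5 without NeuroD1 replicate 2.

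Reactive astrocyte lists were not called. The pan-reactive list had a median of 0.0049, or -0.082 with upper quartile scaling, and 1 of 14 members past the threshold over the list alone (the adhesion receptor gene Cd44, 2.52-fold higher), and the A1-type list a median of 0.21 with C3 alone (1 of 12, 1.84-fold higher; camera adjusted p = 0.936 and 0.0873). In the A2-type list (median 0.19, adjusted p = 0.634) 2 of 11 were higher and 2 lower, led by the cytokine gene Clcf1 (3.65-fold lower) and the membrane protein gene Emp1 (4.26-fold higher), each with an adjusted p of 0.0093. Without GFP replicate 2, GFP replicate 3 or NeuroD1 replicate 1, 0 members passed over the list alone in the pan-reactive and A1-type lists, and 1 higher and 1 lower in the A2-type list. Without NeuroD1 replicate 3, 4 pan-reactive and 4 A1-type members were higher. Without GFP replicate 1 the pan-reactive list had 1 higher and 2 lower and the A1-type list 0, and without NeuroD1 replicate 2 the A2-type list had 3 higher and 1 lower. The A1-type list was called without GFP replicate 2 (median 0.36, adjusted p = 0.0173), GFP replicate 3 or NeuroD1 replicate 1, against adjusted p from 0.633 with an estimated correlation. It was also called with no filter (adjusted p = 0.646 with an estimated correlation) and with the length and GC offsets (adjusted p = 0.0381; 0.55 with an estimated correlation). Its median was 0.029 without GFP replicate 1, 0.10 without NeuroD1 replicate 2 and 0.34 without NeuroD1 replicate 3. The A2-type median was 0.074 without GFP replicate 2, 0.080 without NeuroD1 replicate 1, 0.46 without GFP replicate 1 and 0.42 without NeuroD1 replicate 3.

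No neuronal list was called. Pan-neuronal markers had a median of -0.058 (camera adjusted p = 0.825), glutamatergic markers -0.071 (0.581), GABAergic interneuron markers -0.032 (0.825) and synapse genes 0.19 (0.825), and 0 of 15, 16, 13 and 24 members passed over the list alone. Leaving out a library gave 2 higher and 1 lower GABAergic members (without NeuroD1 replicate 2) and 1 lower glutamatergic member (without NeuroD1 replicate 3). The pan-neuronal mean was 0.03, so mean and median differ in sign, and its median was 0.085 with the length and GC offsets. The neurofilament gene Nefm averaged 68.2 ± 24.0 CPM with NeuroD1 and 88.4 ± 27.1 with GFP, and Nrgn, a postsynaptic protein gene of cortical neurons, 1042 ± 490.1 against 1992 ± 58.2 CPM (adjusted p = 0.277 over the list alone). The pan-neuronal mean of NeuroD1 replicate 2 was -0.97, against 0.19 and 0.58 in replicates 1 and 3. Without that library the pan-neuronal list had a median of 0.29 (adjusted p = 0.0459) and the synapse list one of 0.43 (adjusted p = 0.00413), both with an adjusted p of 0.796 with an estimated correlation. The synapse median was 0.40 without GFP replicate 1, 0.024 without GFP replicate 2, 0.059 without NeuroD1 replicate 1 and 0.011 without NeuroD1 replicate 3. Among proneural and immature neuron genes (median -0.45, adjusted p = 0.109) 1 of 19 was higher, Neurod1 itself (with 1 lower member without GFP replicate 1). The list passed as lower without any 1 of GFP replicate 3 and NeuroD1 replicates 1 and 3 (adjusted p from 0.0402, and from 0.678 with an estimated correlation). Igfbpl1 and Stmn1, genes of immature neurons, had log2 fold changes of -2.26 (SE 0.65) and -0.63 (SE 0.25) without passing (adjusted p = 0.0746 and 0.179), with Igfbpl1 at -1.41 without GFP replicate 2.

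Activity-regulated genes (median -0.048, adjusted p = 0.488) held 1 lower member of 16, the immediate-early gene Nr4a1 (2.19-fold, adjusted p = 0.0292 over the list alone). The list was called without NeuroD1 replicate 1 (adjusted p = 0.0426; 0.664 with an estimated correlation). Its lower members over the list alone numbered 2 without GFP replicate 1, with upper quartile scaling, with no filter or without Rn45s, and 2 beside 2 higher without NeuroD1 replicate 2. They numbered 0 without GFP replicate 2, GFP replicate 3, NeuroD1 replicate 1 or NeuroD1 replicate 3 and with the length and GC offsets. Heat shock and stress genes (median 0.40, adjusted p = 0.428) held 1 lower member of 16, the stress transcription factor gene Ddit3 (2.08-fold, adjusted p = 0.0068), while DESeq2 called 3 higher and 1 lower. The list was called with the length and GC offsets (adjusted p = 0.0331; 0.55 with an estimated correlation), had 3 higher members over the list alone without NeuroD1 replicate 3 and 2 with no filter, and 0 past the threshold without GFP replicate 3. Its median was 0.26 without GFP replicate 1 and 0.27 without NeuroD1 replicate 2. Among neurotrophic factors and receptors 2 of 12 were higher and 3 lower, with a median of 0.079, or -0.0053 with upper quartile scaling, although camera's direction was down (adjusted p = 0.766). They included Fgf1 and Ntrk3, 1.76-fold lower each (adjusted p = 0.0275 each over the list alone). The counts of higher and lower members were 0 and 2 without GFP replicate 1 or GFP replicate 3, 0 and 1 without GFP replicate 2, 0 and 0 without NeuroD1 replicate 1, 1 and 2 without NeuroD1 replicate 2, and 1 and 3 with upper quartile scaling or the length and GC offsets. Oxidative phosphorylation genes had a median of -0.025 (adjusted p = 0.825) with 0 of 21 members past the threshold.

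The choroid plexus and ependyma list, for tissue outside the cortex, and measures of the libraries also differed between samples. Choroid plexus and ependyma markers were lower with NeuroD1 (median -1.38, camera adjusted p = 0.00111; adjusted p = 0.684 with an estimated correlation), with 0 of 9 members past the threshold over the list alone. With upper quartile scaling 7 of 9 were lower by that criterion, with no filter 5 of 12, and without NeuroD1 replicate 3 4 of 11. Ttr, the main choroid plexus transcript, chosen after its values were seen, was at 309.1 ± 413.9 CPM with GFP (784.3 in GFP replicate 2) and 10.3-fold lower with NeuroD1, where the groups overlapped. It was 2.39-fold lower without GFP replicate 2 and 24.0-fold lower without NeuroD1 replicate 2. Striatum markers and thalamus and hippocampus markers were not called (medians 0.38 and -0.033; adjusted p = 0.496 and 0.997), with 0 of 11 and 0 of 9 members past the threshold. The striatum median was 0.13 without GFP replicate 2 or NeuroD1 replicate 1 and 0.17 without NeuroD1 replicate 3. The ribosomal RNA precursor Rn45s took 1.22%, 7.25% and 0.752% of the counts in GFP replicates 1, 2 and 3 and 0.753%, 0.344% and 0.22% in the NeuroD1 replicates. Log2 fold changes across genes correlated with transcript length (Spearman's rho 0.29) and GC content (-0.30), as a property of these libraries, since genes are not independent replicates. Among the 2954 genes with the shortest transcripts the median log2 fold change was -0.25 and among the 2952 with the longest 0.28, and 72 of 76 ribosomal protein genes, which are short and were looked at after the data were seen, had lower fitted levels (median -0.58, and -0.33 without GFP replicate 2). Over the list alone 0 of these 76 passed, with 26 lower without GFP replicate 1 and 1 without NeuroD1 replicate 2.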

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

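The tests chosen only after the data were seen were those with length and GC offsets, without Rn45s, with a robust prior variance, every alternative to the DESeq2 count, the counts over the list alone for 5 lists picked after their values were seen, with all their alternatives, the enrichment among DESeq2 calls, the estimated correlation under alternatives of the fit, and the added lists. Counting members over the list alone was itself fixed before. With the alternatives to the edgeR test, the count of genes was 0 with size factors, upper quartile scaling, either filter, limma-voom, the offsets, without Rn45s, with the robust prior and at adjusted p under 0.1 or 0.01. It was 1374 with DESeq2 (3564 genes had an unadjusted edgeR p under 0.05), 0 to 1 leaving out a library (1 without NeuroD1 replicate 2) and 479 with a replicate block (218 higher, 261 lower). The block gave Neurod1 a log2 fold change of 2.58 (adjusted p = 0.0447) and 11 called lists, without the oligodendrocyte list (adjusted p = 0.0542). Over the list alone it gave 6 lower choroid plexus members against 0, 6 higher complement members against 0 and 7 higher oligodendrocyte precursor members against 2. Same-number replicates correlated at 0.54, 0.37 and 0.04. GFP replicates 1 and 2 correlated best with their own number and GFP replicate 3 did not, so these correlations do not settle pairing. The labels state no pairing, so the numbers were not taken as pairs. The Neurod1 log2 fold change was 2.71 with DESeq2 and 2.33 to 3.04 leaving out a library (adjusted p 0.0421 to 0.412). The DESeq2 count was 162 (without GFP replicate 2) to 2380 (without NeuroD1 replicate 3) and 2448 with the block, and 1342 with the offsets. Called lists went from 12 to 0 with an estimated correlation (0 under every alternative fit too, smallest adjusted p = 0.55) and 0 with fry, and were 8 to 17 leaving out a library. Counts over the list alone were, leaving out a library, 0 to 16 for endothelial, 0 to 8 for pericyte (3 with the offsets), 0 to 10 for scar matrix (0 with the block), 5 to 12 for myeloid and 0 to 15 for cell cycle genes. Lists enriched among DESeq2 calls went from 5 to 9 at adjusted p under 0.1. Over the 31 list medians, 405 of 496 alternative values kept direction and side of the threshold, 24 passed it newly, 34 no longer passed and 33 changed sign. Over 131 named genes, 1979 of 2095 kept both, 115 passed newly and 1 changed sign. Since 0 genes passed in the main fit, keeping the side of the threshold here meant not passing again, so it does not measure robustness. The log2 fold change of C1ql2 went from -3.51 to between -4.07 and 0.14 leaving out a library (0.14 without GFP replicate 2). Medians that changed sign leaving out a library ranged from -0.44 to 0.29 (pan-neuronal), -0.28 to 0.21 (glutamatergic), -0.37 to 0.42 (GABAergic), -0.16 to 0.054 (activity-regulated), -0.098 to 0.080 (pan-reactive), -0.032 to 0.62 (angiogenesis), -0.039 to 0.067 (oxidative phosphorylation), -0.21 to 0.085 (neurotrophic), -0.064 to 0.11 (thalamus and hippocampus) and -0.016 to 0.36 (cholesterol synthesis, an added list). With the offsets the medians were 0.085 (pan-neuronal), 0.14 (GABAergic), 0.11 (activity-regulated), -0.057 (pan-reactive), 0.18 (oxidative phosphorylation) and -0.079 (neurotrophic). The pan-reactive median was -0.082 with upper quartile scaling, -0.015 with the block and -0.018 without Rn45s, and the neurotrophic median -0.0053 with upper quartile scaling and -0.076 with no filter. Leaving out a library also leaves fewer samples to test, and otherwise the cause was not tested. With no filter, 1 cytokine member was higher and 1 interferon member higher and 2 lower over the list alone, and 1 interferon member was lower with upper quartile scaling or the offsets. List enrichment among edgeR calls, planned before, was not run because there were 0 calls. In simulated data of this depth and dispersion, genes varied independently and the changed ones had a mean above 5 CPM. There the edgeR test recovered 10.2% of 2-fold and 88.4% of 4-fold changes. A count of 0 therefore says little about 2-fold changes. It does not speak against larger changes in these libraries either. Cd36, 13.8-fold higher, and Neurod1, with a log2 fold change of 2.68, each had an edgeR adjusted p of 0.136.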

Other observations

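The 8 gene lists added here, the dilution test, the choice of NeuroD1 replicate 2 as an explanation and the splits for counts of genes were chosen only after the results were seen, unlike leaving out each library and the splits for lists.

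Lipid uptake and storage genes of foam cells were higher with NeuroD1 (median log2 fold change 1.58, camera adjusted p = 9.05e-09 over the 8 added lists; adjusted p = 0.213 with an estimated correlation), with 10 of 11 members past the threshold over the list alone. The scavenger receptor gene Cd36 was 13.8-fold higher (248 ± 212.7 against 18.0 ± 9.32 CPM, SD, n = 3) and Msr1 5.16-fold higher (7.11-fold and 2.87-fold without NeuroD1 replicate 2), while the fatty acid binding protein gene Fabp5 did not pass (log2 fold change 0.34, SE 0.35). Leaving out a library gave medians of 1.12 to 1.90 for this list, with 9 or 10 members past the threshold. Toll-like receptor genes had a median of 1.06 (adjusted p = 3.56e-07; 0.213 with an estimated correlation) with 7 of 11 higher, among them Tlr8, an endosomal RNA sensor, 8.81-fold (30.3 ± 16.1 against 3.42 ± 0.251 CPM) and Tlr7 2.20-fold, and 5 to 7 members passed when a library was left out. Fry's directional test passed the Toll-like receptor, circadian clock and histone lists (adjusted p = 0.0431 each) and not the other 5. Because these 8 lists were chosen after results of the same data were seen, their p-values, above and below, are not independent support. They cannot be set beside those of the lists fixed before.

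Axonemal genes of motile cilia were lower (median -1.27, adjusted p = 4.33e-05; 0.255 with an estimated correlation), with 4 of 10 past the threshold over the list alone, among them Spag17, a cilium motility gene (log2 fold change -2.03, SE 0.55). That count was 0 without GFP replicate 2, GFP replicate 3, NeuroD1 replicate 1 or NeuroD1 replicate 2, and 9 without NeuroD1 replicate 3. Leaving out a library gave medians of -1.87 to -0.93. Circadian clock genes were lower (median -0.35, adjusted p = 0.00371; 0.213 with an estimated correlation), with 4 of 16 past the threshold, led by the clock repressor gene Ciart (-1.45, SE 0.28) and Per3 (-0.88, SE 0.23). The clock call was lost without GFP replicate 1 (adjusted p = 0.0601), where 2 members passed, and 0 passed without GFP replicate 2, GFP replicate 3 or NeuroD1 replicate 1. The times of day at which tissue was taken are not given. Ribosomal protein genes had a median of -0.58 (adjusted p = 5.29e-11; 0.303 with an estimated correlation) with 0 of 76 past the threshold over the list alone (26 lower without GFP replicate 1 and 1 without NeuroD1 replicate 2), and medians of -0.33 without GFP replicate 2 and -0.26 with length and GC offsets. Clustered histone genes had a median of -0.39 (adjusted p = 0.0454; 0.213 with an estimated correlation) with 0 of 10 past the threshold (2 lower with upper quartile scaling), and were not called without GFP replicate 1 (0.156), GFP replicate 2 (0.0524), NeuroD1 replicate 2 (0.0772) or NeuroD1 replicate 3 (0.0843). Notch pathway and cholesterol synthesis genes were not called (medians -0.22 and 0.19; adjusted p = 0.106 and 0.143), with 0 of 6 and 0 of 16 past the threshold. The cholesterol list was called at the preset correlation without NeuroD1 replicate 2 (median 0.36, adjusted p = 0.00398; 1 member higher). With an estimated correlation its adjusted p was 0.613 in the main fit. Without NeuroD1 replicate 3, 1 Notch member was lower.

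Itga4 lies within 500 kb of Neurod1 and had the 4th smallest edgeR p of all tested genes (unadjusted p = 9.84e-05, adjusted p = 0.136, log2 fold change 1.56, higher in 3 of 3 NeuroD1 libraries). The other tested neighbours had log2 fold changes of 0.34 (Cerkl, SE 0.58), 0.23 (Ssfa2) and 0.88 (Pde1a), with unadjusted p = 0.577, 0.401 and 0.0868. These neighbours were looked at after their values were seen, and no explanation was tested.

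The medians of endothelial and pericyte genes were lower with NeuroD1, with list means that did not overlap between the groups for endothelial genes and did for pericyte genes (exact permutation p = 0.2), where 3 of 13 members had higher fitted levels. A trend with transcript length and GC content between libraries would shrink this difference once removed, but with the offsets the endothelial median was -0.898 (camera adjusted p = 6.75e-10 at the preset correlation; adjusted p = 0.55 with an estimated correlation) and the pericyte median -0.643. These medians argue against that trend as their whole cause, although 3 pericyte genes were lower over the list alone with the offsets, against 8 without. Dilution by RNA of immune and scar cells stays open and cannot be told apart: it would lower endothelial and neuronal genes alike, and the endothelial minus pan-neuronal mean differed by -0.857 with an exact permutation p of 0.3, because NeuroD1 replicate 2 (-0.12) lay within the GFP range of -0.51 to 0.78. A response of vessels to NeuroD1 may also explain the difference, but depth was higher in every NeuroD1 library, and the means of choroid plexus and ependyma markers (median -1.38) and motile cilia genes (-1.27) were lower in every NeuroD1 library too, so a difference in depth or dissected area stays open.

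The medians of myeloid, scar matrix and cell cycle genes were higher with NeuroD1, with list means that did not overlap for myeloid and cell cycle genes and did for scar matrix genes (exact permutation p = 0.2), where 10 of 15 members passed over the list alone. With the length and GC offsets the lowest of the 3 medians was 1.19 and the myeloid median 1.41 (adjusted p = 0.55 for each list with an estimated correlation), which argues against the length trend as the whole cause. Without NeuroD1 replicate 2, which had the highest means, the lowest median was 0.760 and the myeloid median 1.17 (largest camera adjusted p = 0.00157 at the preset correlation; adjusted p = 0.796 for each list with an estimated correlation), which argues against that library as the only source. A larger or more inflamed lesion in the sampled tissue, at similar time or not, and a response to NeuroD1 or its delivery may each explain the rest, and the labels give no measure that would separate them.

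Among the 10 splits of the 6 libraries into 3 against 3, the share with a result as large as the real one is never under 0.1. At edgeR's adjusted threshold the real split gave 0 genes and the highest other 0, so 10 of 10 splits are as large by construction and the comparison carries no information. The real split gave 3564 genes at an unadjusted p under 0.05 and 1374 with DESeq2 (1 of 10 each), against 2756 and 1110 for the highest other. That other split set GFP replicate 1 and NeuroD1 replicates 1 and 3 against the rest, which points to a structure of the samples besides treatment: the pan-neuronal mean was 0.35, 0.19 and 0.58 in these libraries and -0.42, 0.07 and -0.97 in the others. For lists called by camera the real split gave 12 and the highest other 20, and 7 of 10 splits gave at least 12.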
